A study of Phaeodactylum tricornutum with 53 samples.

How the data were processed

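Transcript levels were measured in cultures of the wild-type diatom Phaeodactylum tricornutum, strain CCMP632. The cultures had been kept in 16 h of light and 8 h of dark for 2 weeks, then divided between that cycle (LD) and continuous darkness (DD). Samples were taken every 4 h over 32 h, from -8 h, when the lights went off, to 24 h, with light onset at 0 h. The labels give 3 biological replicates (A, B and C) per regime and list 53 samples, with no LD sample at 4 h for replicate B. The panel held 104 tested transcripts and 3 reference genes, Actin12, Rps and Tbp.

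Per the labels, unlabelled total RNA was hybridised to gene-specific probes with biotin and fluorescence tags. The deposited per-series files hold linear signal values that the authors had not divided by the reference genes. The deposited value table holds log2 values. In the 44 samples outside the DD series of replicate A, 4569 of 4569 transcript values compared equalled the log2 of signal over the geometric mean of the 3 reference genes within 0.002, once 6 names that differ or are exchanged had been matched by their values. CCT3 and CCT4 are exchanged between table and files, and the names of the files were used. The 7 values not compared are empty in the table and 0 in the files. How the signal was scaled and whether background was removed is not stated. In those 44 samples every signal was a whole number of steps of 0.7125 to 1.6064 per sample, within a tolerance of 0.001 steps, so the step count served as the measure of depth. No genome build comes with the series, and 17 of the 107 symbols matched a symbol in the RefSeq table given, so transcripts are named by the symbols of the files and carry no positions.

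For the DD series of replicate A the per-series file and the value table differ. The value-table column of a sample equalled the preceding column of the file for 784 of 784 transcript values compared, and its own column for 1 of 882, within 0.002 on the log2 scale. The tested transcripts of that series were therefore rebuilt from the value table and the reference-gene signals of the same sample, and the values as the file labels them were run as an alternative.

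Each signal was divided by the geometric mean of Actin12, Rps and Tbp in its sample, brought back to the mean level of that factor, and expressed as log2 with a pseudocount of 1. The test planned for whole counts was not used, because the unit is signal. The replacement planned for that case, limma on the log2 values, was used throughout. The planned filter, by negative controls or for whole counts, did not apply to these values either. In its place, and not as planned, a signal of at least 10, scaled to the sample total, was required in at least 2 samples. This removed 0 of the 104.

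The model had 1 mean for each of the 18 combinations of regime and time, with 35 residual degrees of freedom, and limma's moderated statistics were adjusted by Benjamini-Hochberg over the 104 transcripts at a threshold of 0.05. Contrasts compared the time courses, the profiles, the light hours (4, 8 and 12 h), the shared dark hours (-8, -4 and 0 h), each time point, and the later night hours (16, 20 and 24 h) with the earlier ones in each regime. The p-values measure the spread between samples. Samples of a series come from the same culture over time and were treated as independent in this model, with the culture series as a random block among the alternatives. Replicate letters were not used to pair LD with DD cultures.

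Rhythms were tested with a cosine of 24 h period fitted in each regime. Amplitude and time of peak were fitted per culture and are given as mean and SD over 3 cultures. A transcript kept its timing when it passed the test in both regimes and its peaks lay within 4 h of each other. Because 32 h cover little more than 1 cycle, the fit describes the phase of a cosine and cannot show that a rhythm persists. Its peak can lie hours from the highest mean, as for PCNA in LD, with 10.7 h fitted and the highest mean at 4 h. Gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and with the two-sided Fisher's exact test for tests without direction.

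The contrasts, thresholds, gene lists, most of the alternatives and the rule for named genes were fixed before the data were examined. That rule names the 10 passing transcripts with the largest range in each time course and in the profile, the 10 largest changes in each direction in the light hours, the shared dark hours and the nights of DD, and up to 20 transcripts with kept timing and the largest DD amplitude. It adds the 2 members of each list with the smallest p in either time course and in the light hours, the extremes at each time, bHLH1a_PAS, bHLH1b_PAS and the reference genes. The difference between the 2 night contrasts was added after the data were seen.

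Tested on simulated data of the same size, the light-hours contrast recovered 47% of changes of 0.5, 90.5% of changes of 1 and 99.5% of changes of 2 on the log2 scale, and 5.58% of its calls were false. With amplitudes of 0.5, 1 and 2 log2, timing was called kept for 66%, 98% and 100% of rhythms without a shift, and for 0% of those shifted by 8 h. The simulated noise was independent between samples and transcripts, whereas real samples of a series share a culture, with a block correlation of 0.222. Changing reference genes and the dark hours shared by the regimes were not simulated, so these rates may not hold for the real data.

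Alternatives were TMM-type and median-of-ratios factors computed by hand, each reference gene left out in turn, the shallow LD 8 h B sample left out, unscaled signal without that sample, other filters, thresholds and pseudocounts, the authors' values, the replicate letter or culture as a block, sample weights, and each culture left out in turn. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The reference-gene entries of the value table were left out, because those of replicate C are relative to another transcript.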

Results

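The data are levels of 104 transcripts and 3 reference genes in 53 samples, from 18 combinations of regime and time. Each combination has 3 cultures except LD at 4 h, which has 2. Depth, as whole signal steps per sample, is known for the 44 samples outside the DD series of replicate A. It ran from 220422 to 1205865 with a median of 692157, apart from LD at 8 h replicate B, which had 4375. The chloroplast transcript psbC took 72.8% to 96.0% of the signal, or 72.5% in that shallow sample, so the other transcripts shared 25495 to 258134 steps per sample, or 1203 in it. In it CCCH8, HSF3.3a, HSF3.3f, HSF4.4b, Myb2R3b and Myb3R2 were at 0, and low transcripts could not be measured precisely. Unscaled signal below means deposited signal that was not divided by any factor here. It still carries each sample's own step, 0.7125 to 1.6064 in the 44 samples, whose origin is not stated. Unscaled signal always leaves the shallow sample out as well. Within a group, log2 profiles of samples correlated across transcripts at r of 0.928 to 0.993 without that sample and at 0.681 at the lowest with it, transcripts not being independent replicates.

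The time course in LD asked which transcripts change over the day. The PAS-domain transcription factor bHLH1a_PAS, the RITMO1 of the series title, was at 9.63 ± 0.09 log2 (SD, n = 3) at -8 h, 5.80 ± 0.40 at 0 h, 9.86 ± 0.27 at 12 h and 5.68 ± 0.23 at 24 h. Its relative bHLH1b_PAS rose from 5.48 ± 0.08 at 0 h to 10.74 ± 0.36 at 12 h and was at 5.17 ± 0.15 at 20 h (SD, n = 3). The stress-related antenna transcript Lhcx1 had the largest range, 8.13 log2, with its highest mean at 4 h and its lowest at -4 h. The ranges of bZIP26 and GapC1 were 8.12 and 8.06, with the highest means at 12 h and 4 h. The PAS-domain factor bZIP5_PAS ran the other way over 6.67, highest at -4 h and lowest at 4 h. Of the 104 transcripts, 90 passed the limma test of equal means over the 9 times. The other transcripts among the 10 largest ranges were Vdl2, bZIP14, HSF3.3a, Myb1R_SHAQKYF6, Gsat and HSF3.3f, between 5.89 and 6.89; without the shallow sample HSF3.3a had 6.36 and HSF3.3f 5.10, no longer among the 10. All 20 heat shock factors and all 12 pigment synthesis transcripts passed, as did 3 of 4 bHLH factors, against 2 of 5 light-harvesting and photosystem transcripts and 4 of 6 photoreceptors, and the counts adjusted over the list alone were 20, 12, 3, 2 and 4.

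**Figure D1:**
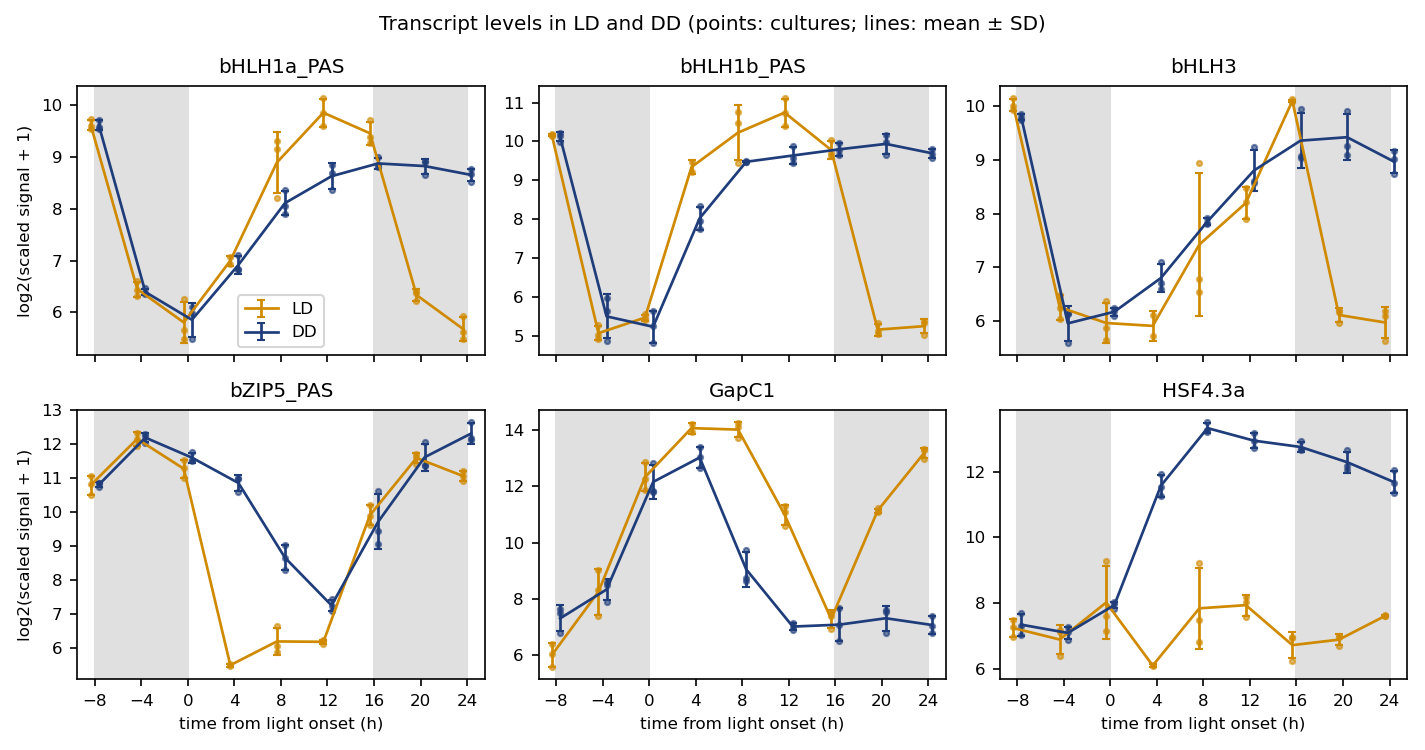
Levels of 6 transcripts as log2 of scaled signal plus 1 against time from light onset in h, in LD and DD. Points are cultures, lines join means, bars are SD, and grey marks the hours that are dark in LD; bHLH1b_PAS at 20 h was at 5.17 in LD and 9.94 in DD.

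In DD the question was which transcripts change over the sampled hours. These include -8 to 0 h, the usual night after a lit day, so changes over that night count as well. The heat shock factor HSF4.4b rose from 3.20 ± 1.07 log2 at -4 h to 11.04 ± 0.22 at 8 h (SD, n = 3), the largest DD range at 7.85. HSF4.3a had a range of 6.25 and reached 13.33 ± 0.16 at 8 h. The xanthophyll-cycle relative Vdr had a range of 6.19 with its highest mean at 8 h. GapC1 still rose to 13.03 ± 0.38 at 4 h in DD, from 8.34 ± 0.38 at -4 h, and was at 7.02 ± 0.12 at 12 h (SD, n = 3). In DD, bZIP5_PAS fell to 7.25 ± 0.17 at 12 h and returned to 12.32 ± 0.30 at 24 h, a range of 5.07. The test of equal means over time was passed by 91 of the 104 transcripts. HSF2.1a, CSF2, PCNA, HSF1d and Cpd2 completed the 10 largest ranges, between 4.96 and 5.94. Of these, CSF2, PCNA and HSF1d had their highest mean at -8 h, before the regimes parted. All 20 heat shock factors, 4 of 4 bHLH factors, 5 of 5 light-harvesting and photosystem and 12 of 12 pigment synthesis transcripts passed, against 8 of 12 Myb factors, 9 of 12 bZIP factors and 4 of 6 photoreceptors, with the same counts adjusted over the list alone. No list had an adjusted p under the threshold in Fisher's exact test, here, in the LD time course or in the profile.

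**Figure D2:**
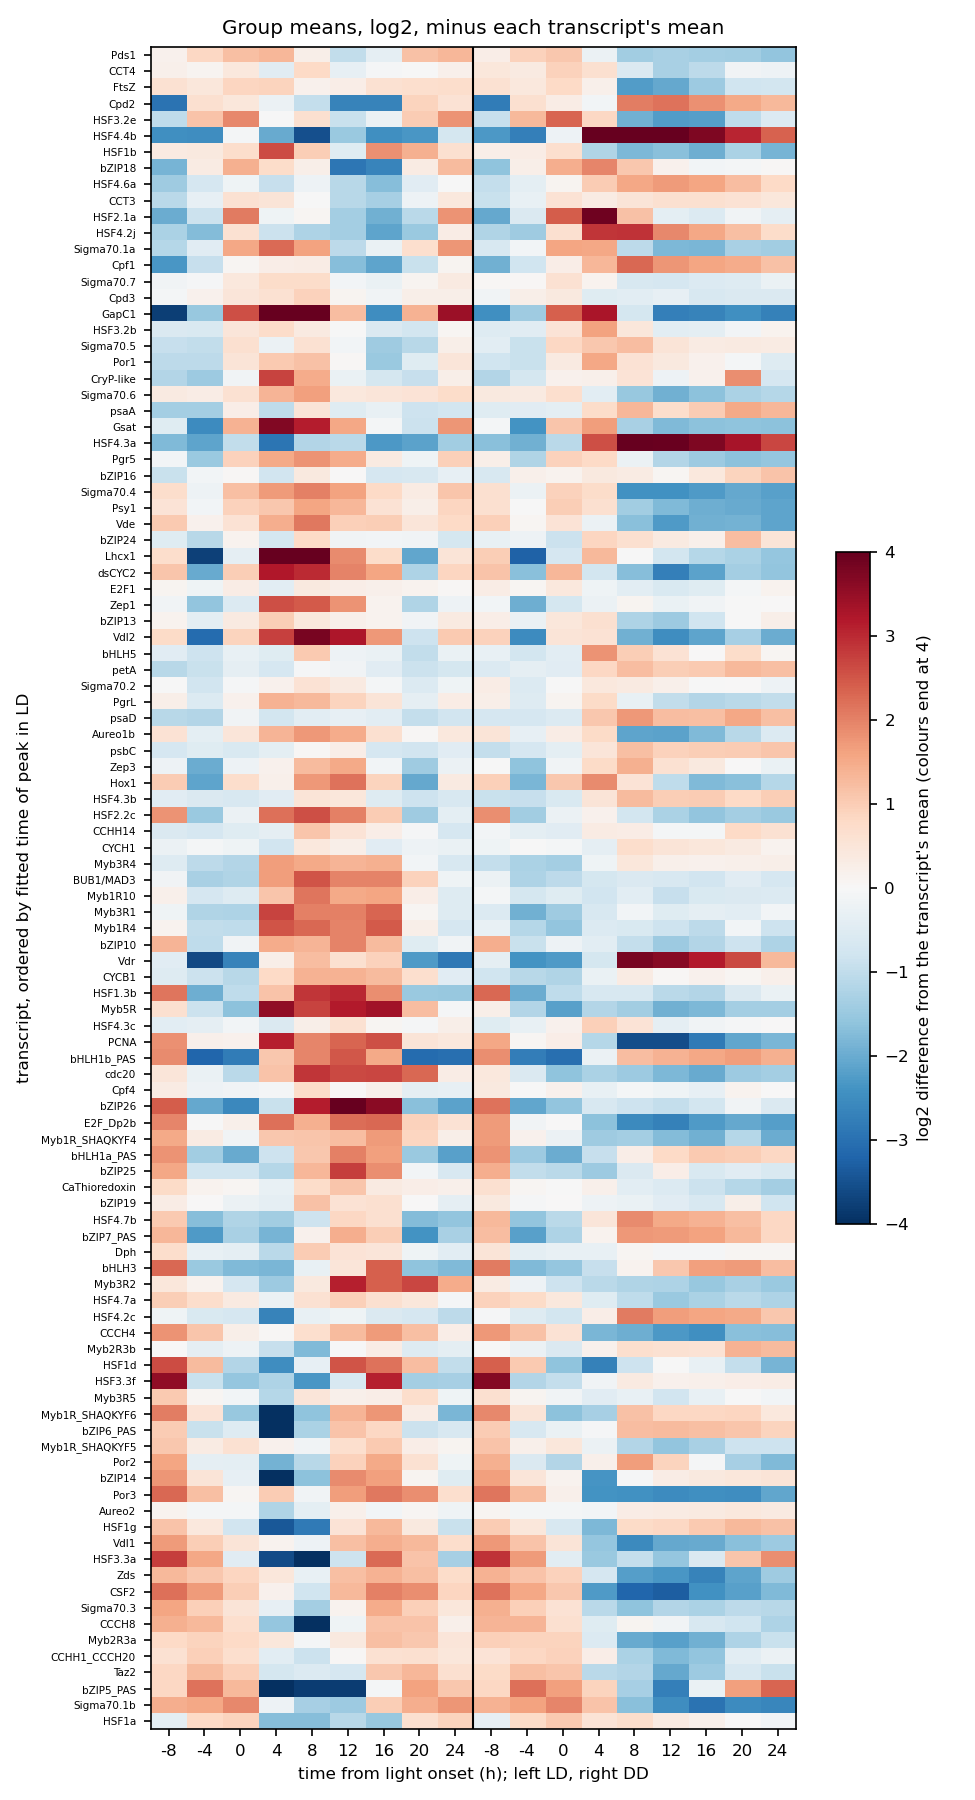
Group means of the 104 transcripts as log2 minus the transcript's own mean, with LD times on the left and DD times on the right in h, ordered by fitted time of peak in LD. From -8 to 0 h both sides look alike, where 0 transcripts passed the limma test in the shared dark hours, and from 4 h they part.

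Levels at 4, 8 and 12 h, when LD cultures were lit and DD cultures were not, address the response to light. The replication clamp PCNA was higher in LD by 5.20 ± 0.18 log2 (SE, 8 LD and 9 DD samples). The cyclin dsCYC2 was higher by 4.45 ± 0.25, the cell cycle factor E2F_Dp2b by 4.25 ± 0.21, and cdc20 by 3.72 ± 0.30. Heat shock factors HSF4.4b and HSF4.3a were lower in LD, with differences of -6.86 ± 0.37 and -5.33 ± 0.23, or -6.46 ± 0.30 and -5.56 ± 0.19 without the shallow sample. Myb5R and Vdl2 were higher by 4.64 ± 0.29 and 4.53 ± 0.24, and bZIP5_PAS was lower, at -2.97 ± 0.16. In all, 89 of 104 transcripts passed, 56 higher and 33 lower in LD. Higher in LD among the 10 largest were also bZIP26, Lhcx1, GapC1 and Por3, at 3.29 to 3.40, and lower were HSF4.2j, Cpd2, bZIP6_PAS, HSF4.2c, Cpf1, HSF4.6a and HSF1a, at -3.71 to -2.04. These 20 directions were the same under every scaling tried. The difference of bHLH1b_PAS was 1.06 ± 0.15 and that of bHLH1a_PAS 0.70 ± 0.13, and under median-of-ratios scaling bHLH1a_PAS turned to -0.047 while bHLH1b_PAS kept its sign and no longer passed.

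The split of the light-hours calls depends on the scaling. Against the median log2 difference of 0.78 under reference-gene scaling, the median was 0.05 under median of ratios, with 43 higher and 43 lower, and 0.25 under TMM. Without the shallow sample it was 0.78, with 54 higher and 35 lower, and on unscaled signal without it 2.23, with 79 and 11. It was 0.46 without Actin12, 1.10 without Rps and 0.78 without Tbp. Of the 89 calls, 74 kept their direction in every scaling, 54 higher and 20 lower. In 43 of the higher and 11 of the lower the test was also passed in every scaling.

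By list, 5 of 7 cell cycle transcripts passed, all 5 higher in LD under every scaling, and 9 of 10 passing pigment synthesis transcripts were higher under every scaling, Por2, named after its value was seen, being lower. Of 11 passing Myb factors 9 were higher, and 10 on unscaled signal. Leaving out the shallow sample alone kept the split of these calls in every list. Of 20 heat shock factors 19 passed, 6 higher and 13 lower, against 10 higher and 9 lower on unscaled signal and 7 higher and 12 lower without Rps. Camera gave the heat shock factors an adjusted p of 0.011, lower in LD, with a median of -1.51, or -0.94 without the shallow sample and 0.50 on unscaled signal, and an adjusted p of 0.317 with an estimated correlation. No other list passed in camera, the cell cycle and pigment synthesis transcripts being at 0.179 each, and 0.753 with an estimated correlation. Lhcx1 was higher while the other 4 light-harvesting and photosystem transcripts were lower, of which psbC and 1 other turned higher on unscaled signal. The 4 bHLH factors divided 2 and 2, but 1 higher and 3 lower under median of ratios and 3 higher and 1 lower on unscaled signal. Passing counts adjusted over the list alone were 5, 10, 11, 19, 5 and 4 for these lists. Of 12 bZIP factors 9 passed, 5 higher and 4 lower, against 6 and 3 on unscaled signal, and 8 passed adjusted over the list alone. Of 6 photoreceptors 4 passed, 2 higher and 2 lower, against 3 and 1 on unscaled signal, and 4 passed adjusted over the list alone.

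**Figure D3:**
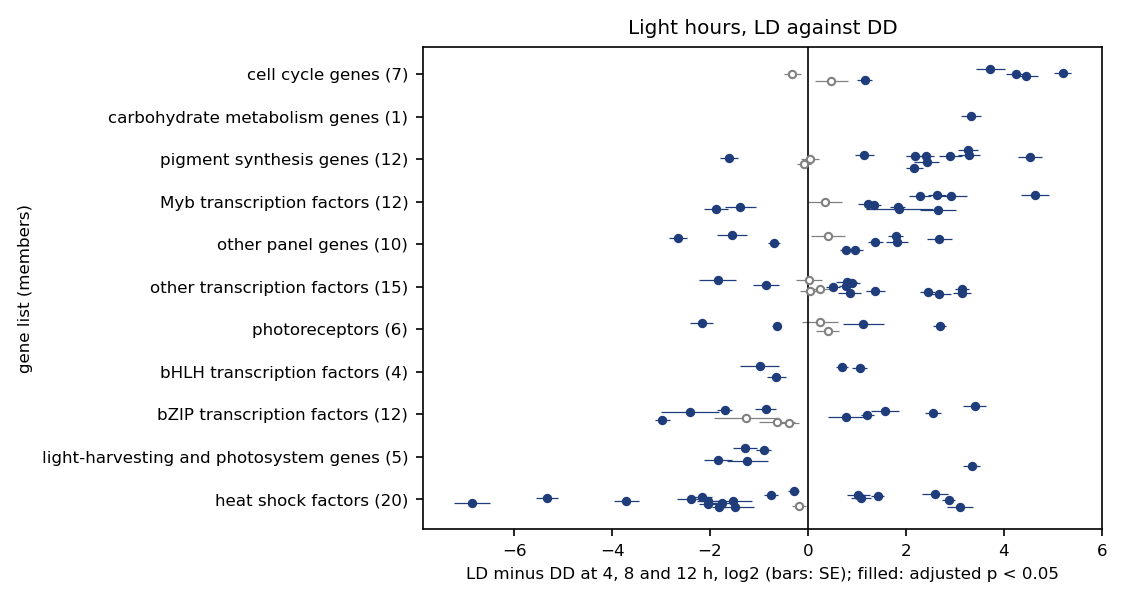
Difference between LD and DD at 4, 8 and 12 h per transcript, as log2 with SE bars, by gene list, with filled points for transcripts past an adjusted p of 0.05. Cell cycle transcripts reach 5.20 and heat shock factors -6.86; 6 passing heat shock factors lie to the right and 13 to the left under reference-gene scaling, and 10 and 9 on unscaled signal.

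Before light onset, at -8, -4 and 0 h, both regimes were in the dark after the same light history. At these hours bHLH1a_PAS differed by 0.01 ± 0.12 log2 and bHLH1b_PAS by -0.05 ± 0.14 (LD minus DD, SE, 9 samples each). Limma found 0 of 104 transcripts, with 3 at an unadjusted p under 0.05. After subtracting these differences from those in the light hours, PCNA was still higher in LD by 5.10 ± 0.24 and HSF4.4b lower, at -6.94 ± 0.51. That contrast was passed by 83 transcripts, 54 higher and 29 lower.

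At single times, the differences between regimes (LD minus DD, SE) began at 4 h, where Myb5R was higher in LD by 4.72 ± 0.53 log2 and HSF4.4b lower, at -6.36 ± 0.69. At 8 h Vdl2 was higher by 5.72 ± 0.41 and HSF4.4b lower, at -8.65 ± 0.62, or 5.53 ± 0.45 and -7.45 ± 0.54 without the shallow sample where PCNA was the highest at 5.68 ± 0.32. At 12 h bZIP26 was higher by 6.48 ± 0.39, and at 16 h PCNA by 5.41 ± 0.29, with HSF4.4b lower at -5.58 ± 0.62 and -6.17 ± 0.62. At 20 h Por3 was higher by 4.34 ± 0.38 and HSF4.3a lower, at -5.41 ± 0.38. At 24 h GapC1 was higher by 6.12 ± 0.35, and bHLH1b_PAS was lower, at -4.44 ± 0.25. The limma counts from 4 to 24 h were 71 (38 higher, 33 lower), 80 (52, 28), 71 (55, 16), 78 (57, 21), 72 (40, 32) and 77 (47, 30). At 8 h the split was 49 and 31 without the shallow sample, with the panel median at 0.32 instead of 0.88, and 76 and 12 on unscaled signal. At -8, -4 and 0 h they were 0, 0 and 0, with 1, 2 and 2 at an unadjusted p under 0.05.

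The hours from 16 to 24 h, set against -8 to 0 h, compare the second night of each culture with the first. In LD the night level of bHLH1a_PAS differed by -0.14 ± 0.12 log2 and that of bHLH1b_PAS by -0.17 ± 0.14 (SE, n = 9 per night), neither passing. Myb5R, cdc20 and GapC1 were higher in the second LD night, by 2.14 ± 0.28, 2.04 ± 0.29 and 1.68 ± 0.20, while bZIP5_PAS was lower, at -0.55 ± 0.15. Of 104 transcripts 21 passed in LD, 20 higher and 1 lower, and all 21 kept their direction in every scaling. Under median of ratios 14 were higher and 9 lower, and under TMM 17 higher and 4 lower. Without LD replicate A, 11 transcripts passed.

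In DD the night levels of bHLH1b_PAS rose by 2.85 ± 0.14 log2 and those of bHLH1a_PAS by 1.50 ± 0.12 (SE, n = 9 per night), the latter no longer passing on unscaled signal. At 20 h in DD, bHLH1a_PAS was at 8.83 ± 0.15, against 6.33 ± 0.11 in LD (SD, n = 3). HSF4.3a and HSF4.4b rose by 4.79 ± 0.22 and 4.78 ± 0.36, and Vdr by 4.03 ± 0.29. The sigma factor Sigma70.1b fell by 4.35 ± 0.25, CSF2 fell by 3.72 ± 0.18, Por3 fell by 3.54 ± 0.22 and PCNA fell by 2.88 ± 0.17. Cpf1, Cpd2, bZIP7_PAS, psaD, bHLH3 and HSF4.2c rose by 1.82 to 2.23, although bZIP7_PAS no longer passed without DD replicate A or C, without Rps or on unscaled signal, at 1.36, 1.73, 1.17 and 0.84. Zds, CCCH4, Vdl1, E2F_Dp2b, Sigma70.4 and Psy1 were lower, at -3.22 to -2.57. The 20 named directions were the same under every scaling tried.

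Of the 104 transcripts 76 passed between the nights of DD, 32 higher and 44 lower, with a median of -0.34 over the panel. The split was 44 and 40 under median of ratios with a median of 0.15, 52 and 35 without Actin12 with 0.51, 19 and 68 without Rps with -1.13, and 14 and 74 on unscaled signal with -1.45. TMM gave 36 and 43. Direction was the same in every scaling for 63 of the 76, and 14 higher and 35 lower transcripts passed in every scaling. Among 4 bHLH factors 3 passed, all 3 higher in every scaling, with a camera adjusted p of 0.0245, and 0.0613 with an estimated correlation. Of the 15 other transcription factors 13 passed, 1 higher and 12 lower, against 2 and 11 without Actin12 and 0 and 13 on unscaled signal, with a camera adjusted p of 0.0128, and 0.297 with an estimated correlation. Counts adjusted over the list alone were 3 and 13. The change between nights differed between DD and LD for 72 transcripts, 26 with a larger value in DD and 46 with a smaller one. This split is under reference-gene scaling and may turn with it. Median night changes in DD and LD were 0.15 and -0.18 under median of ratios, but -1.45 and 0.19 on unscaled signal. For bHLH1b_PAS the difference between DD and LD was 3.02 ± 0.20 and for bHLH1a_PAS 1.64 ± 0.18 (SE, reference-gene scaling).

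The profile test asked which transcripts follow a different time course in the regimes. HSF4.4b had the largest range of the LD minus DD difference, 8.89 log2, followed by bZIP26 at 8.04 and GapC1 at 7.42. The GapC1 difference was lowest at -8 h, before the regimes parted, at -1.30 ± 0.35 (SE), and did not pass there. Its range thus includes a difference between cultures at that hour. For bHLH1b_PAS the range was 6.09, with the difference highest at 4 h and lowest at 20 h. CCCH8, Vdl2, HSF2.1a, HSF4.3a, HSF3.3a and PCNA ranged from 5.97 to 6.39. Without the shallow sample bZIP26 came first, and HSF4.4b had 7.69 and CCCH8 4.61. The limma test was passed by 89 of 104 transcripts, among them 20 of 20 heat shock factors and 12 of 12 pigment synthesis transcripts, but 8 of 12 bZIP factors and 4 of 6 photoreceptors, with the same counts adjusted over the list alone.

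The series was designed to find transcripts that are not regulated by light, so times of peak were compared between regimes. GapC1 peaked at 4.56 ± 0.36 h in LD and 3.70 ± 0.29 h in DD (SD, n = 3 cultures). The peaks of bZIP5_PAS were at 20.4 ± 0.45 h and 22.5 ± 0.48 h. For bHLH1a_PAS they were at 12.1 ± 0.52 h and 13.9 ± 0.31 h, and for bHLH1b_PAS at 10.8 ± 0.66 h and 12.2 ± 0.28 h. The DD amplitude was 46.7% of that in LD for bHLH1a_PAS and 43.0% for bHLH1b_PAS. HSF2.1a peaked at 2.40 ± 0.95 h and 4.22 ± 0.39 h with a DD amplitude of 102% of that in LD.

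The limma test of a 24 h cosine was passed by 81 transcripts in LD and 55 in DD, and by 46 in both. Timing was kept by 36 of the 46, with a median absolute shift of 1.31 h, 21 later and 15 earlier in DD. The DD amplitude was smaller in 29 of them, and its median was 68.4% of the LD amplitude. The 36 include the 4 bHLH factors (bHLH5 in 7 of 23 other settings), 8 of 20 heat shock factors, 5 of 12 bZIP factors, 1 of 12 Myb factors and 0 of 7 cell cycle transcripts, but no list had an adjusted p under the threshold in Fisher's exact test. Besides those above, the 20 with the largest DD amplitudes were Vdr, CSF2, HSF3.2e, HSF1d, HSF3.3a, bZIP7_PAS, Hox1, Por3, Vdl1, Myb1R_SHAQKYF6, bZIP18, Sigma70.1a, bHLH3, HSF4.7b and Lhcx1. Of these, CSF2, Por3, Vdl1, HSF1d, HSF3.3a, Myb1R_SHAQKYF6 and bHLH3 had their highest DD mean at -8 h, before the regimes parted. Mean night levels of CSF2, Por3 and Vdl1 in DD fell from 9.98 to 6.25, 7.97 to 4.42 and 9.10 to 6.25 log2. Those of HSF1d, HSF3.2e, Hox1 and Sigma70.1a fell from 8.90 to 7.26, 7.12 to 4.96, 8.95 to 7.36 and 6.69 to 4.91. A 24 h cosine can also fit such a decline. Vdr, bHLH3, bZIP7_PAS and HSF4.7b were higher in the second night of DD. HSF3.3a, Myb1R_SHAQKYF6, bZIP18 and Lhcx1 did not pass between these nights. In 10 transcripts the peaks lay over 4 h apart, among them PCNA at 10.7 ± 1.20 h in LD and 21.2 ± 0.52 h in DD. Only the LD test was passed by 35 transcripts, only the DD test by 9, and neither by 14. With times from 4 to 24 h alone 23 transcripts kept their timing, 20 of them among the 36. GapC1, bZIP5_PAS and bHLH3 were among these 20, and bHLH1a_PAS, bHLH1b_PAS and bHLH5 were not.

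**Figure D4:**
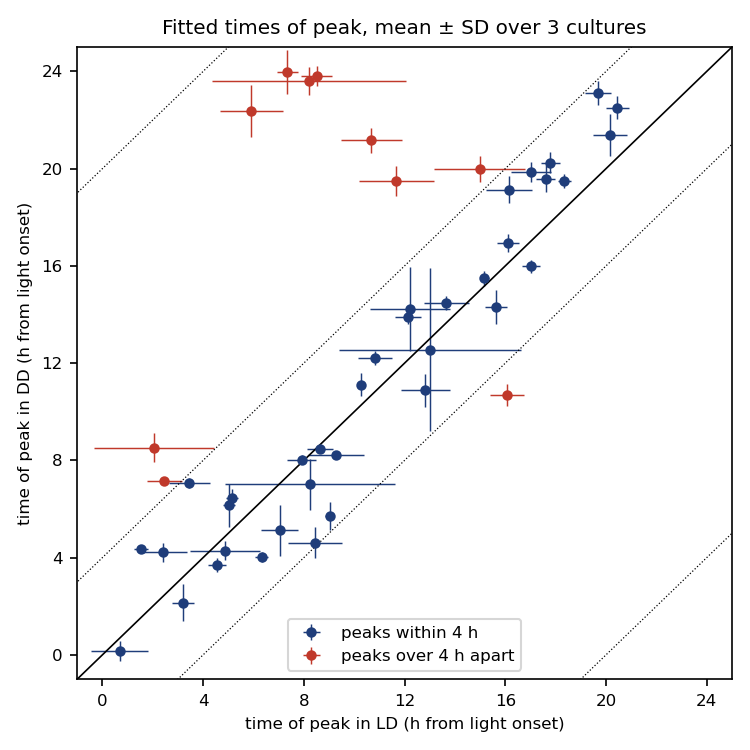
Fitted time of peak in DD against that in LD, in h from light onset, for the 46 transcripts that passed the 24 h cosine test in both, as mean and SD over 3 cultures. The solid line marks equal times and the dotted lines 4 h; 36 transcripts lie within them and 10 outside.

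The reference genes themselves differed in deposited signal. Rps was higher in LD than in DD in the light hours by 2.15 ± 0.20 log2 and Tbp by 1.65 ± 0.17, against 0.63 ± 0.27 for Actin12 (SE, without the shallow sample). From the first to the second night of DD, Rps fell by 2.72 ± 0.18 and Tbp fell by 1.23 ± 0.16, while Actin12 rose by 0.57 ± 0.25. In LD none of the 3 passed the limma test between nights, with differences of 0.22, 0.03 and 0.25 for Rps, Tbp and Actin12.

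**Figure D5:**
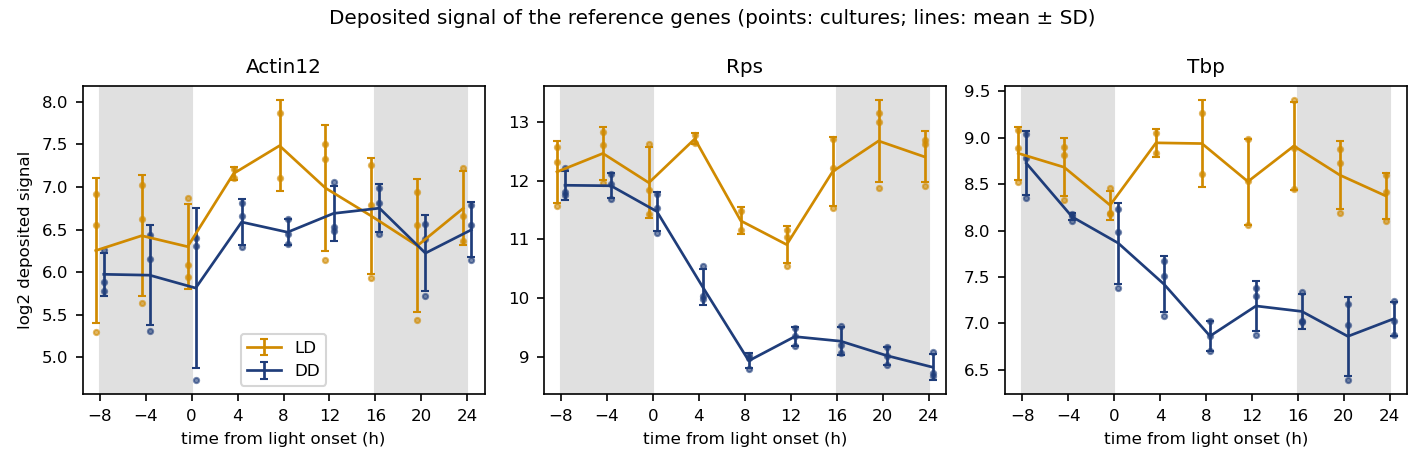
Deposited signal of the 3 reference genes as log2 against time from light onset in h, with cultures as points and mean and SD as lines and bars, without the shallow LD sample at 8 h. In DD Rps falls from 11.92 at -8 h to 8.83 at 24 h, while Actin12 stays between 5.81 and 6.75.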

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

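The tests of the DD series of replicate A, of the reference genes, of scaling and of the first hours in kept timing, of the difference between the night contrasts, and of the opposite night changes were chosen after the results were seen, while the other splits and the random pairing of peaks were planned.

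The change from the first to the second night differed between DD and LD in 72 transcripts. Of 100 splits of the samples 1, the real one, gave as many and the highest other gave 53, so a random split of single samples was excluded. In 8 transcripts the night change passed in both regimes with opposite signs, higher in LD and lower in DD, but chance is not excluded for the LD calls, and over 23 other settings the count ran from 0 with DD A as labelled to 17 on unscaled signal without the LD 8 h B sample. It was 4 without LD replicate A, under median of ratios only 4 of the 8 were shared, and E2F_Dp2b and Pgr5 were opposite in 14 and 15 settings. HSF1b and Pgr5 are outside the naming rule and were picked after their values were seen. The difference (DD minus LD, log2) was -3.79 for GapC1, -3.25 for E2F_Dp2b, -3.05 for cdc20, -2.92 for HSF1b, -2.57 for Vdl2, -2.51 for Sigma70.1a, -2.13 for Pgr5 and -1.98 for Gsat. The profile over all times differed between regimes in 89 transcripts, with 78 as the highest other of 100 splits and 1 split as large.

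Splits of single samples exclude chance at that level for most other counts, each with 1 of 100 splits as large; a regime belongs to whole cultures, whose splits are too few to decide. The real and highest other counts were 89 and 81 for the light hours, 83 and 50 for the response net of the shared dark hours, 76 and 69 for the nights of DD, 90 and 73 for the LD time course, 91 and 66 for the DD time course, 81 and 25 for the LD rhythm, 55 and 51 for the DD rhythm, and 36 and 0 for kept timing. The splits for kept timing also break the link that the shared dark hours give to the LD and DD fits. Chance was not excluded for the nights of LD, where 21 transcripts passed, 10 of 100 splits gave as many and the highest gave 49. For the nights of LD and of DD the splits also shuffled the hours within a night. Changes over the night thus entered these counts, and the splits do not compare the nights at matched hours. In the shared dark hours the count was 0, so all 100 splits had to give as many and cannot decide anything. The highest gave 5.

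Single times and whole cultures allow 10 splits each, too few for a share under 0.05, and 4 h, with 2 LD samples, was not split. The real and highest other counts were 0 and 0 at -8 h, 0 and 0 at -4 h, 0 and 1 at 0 h, 80 and 33 at 8 h, 71 and 3 at 12 h, 78 and 0 at 16 h, 72 and 0 at 20 h, and 77 and 0 at 24 h. With whole cultures regrouped, the light hours gave 89 and 13.

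The DD series of replicate A differed between the deposited file and the value table, and 104 of 104 transcripts in the file's DD 24 h column equalled LD 24 h of replicate A. The values argue against a mislabelled value table, whose columns correlated better across transcripts with the mean of DD replicates B and C at 9 of 9 times. A candidate explanation is that the transcript values stand 1 column early in the file while the reference values do not. In line with it, 24 of 24 reference values were whole in the step of the preceding column and 0 of 27 in that of their own. No biological explanation was tested.

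Deposited signal of Rps and Tbp, outside the tested panel, was lower in the second night of DD, with differences between DD and LD in the night change of -2.94 and -1.26 log2. Less RNA in the later hybridisations is argued against as the whole cause by Actin12, which rose by 0.57 ± 0.25 (SE) over the same hours, most of it in replicate B, at 1.15 against 0.27 in A and 0.30 in C. The signal of psbC rose as well, by 0.60 ± 0.23. Actin12 was low, however, at 22 steps in DD at 0 h replicate B. On unscaled signal most of the panel fell with Rps and Tbp, with a median of -1.45, 74 transcripts passing lower and 14 higher. Less RNA as a part of the cause therefore stays open. A single culture is argued against, since Rps fell by over 1 log2 in 3 of 3 DD cultures, by values of -2.85, -2.37 and -2.96. For darkness, the regime of the labels, the -2.94 of Rps met the bound set for it. That value is the pattern itself, and the bound was written after it was seen, so the test could not fail. Regulation of these transcripts in the dark was not told apart from other differences between DD and LD cultures. Whether Actin12 is steady is open, and Rps moved within LD as well, from 12.71 at 4 h to 10.91 at 12 h, so every scaled level, range and peak carries this doubt.

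Timing was kept by 36 transcripts, against a median of 16 and a highest value of 29 when LD and DD peaks were paired at random (1-sided permutation test, p of 1e-05, the smallest that 100000 draws can give). Both fits include the dark hours from -8 to 0 h, which the regimes share, so agreement above random pairing is partly built in. In DD, bHLH1a_PAS and bHLH1b_PAS even had their highest and lowest means at -8 and 0 h. The pairing test therefore cannot show that timing was kept without light. Division by changing reference genes is argued against as the whole cause, since 33 of the 36 were kept under median of ratios, although 25 were kept on unscaled signal without the LD 8 h B sample, against 33 without that sample alone, and 24 in all 6 other scalings. A response to the first hours after transfer stays open, since 20 of the 36 were kept with the last 24 h, or 55.6% with an exact Clopper-Pearson 95% interval of 38.1% to 72.1%. The bound set for excluding it was over 50%, which this interval includes. The interval was brought in after the value was seen, and by the bare count the bound was passed. It also treats transcripts of the same cultures as independent, which they are not. The last 24 h still hold 4 h, where GapC1 had its highest DD mean. Neither the interval nor the count can therefore decide on a response to the first hours. A clock that runs without light may explain these peaks, but 1 cycle cannot tell it apart from such a response.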

How the results depend on the processing

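Chosen after the data were seen were the tests without the LD 8 h B sample, on unscaled signal, with the DD A series as its file labels it, with sample weights (REML first, whose iterations did not converge, then gene by gene, tried because of that once the REML counts were known), and with pseudocount 10. Positive spike-in scaling and DESeq2 were not run, as there are no spike-in values and the unit is signal. The filter removed 0 transcripts, so leaving it out tests nothing. Values of 56 named genes in the time courses, the light hours and the nights of DD were followed over 22 alternatives. Of 4928 values, 4738 kept their side of the threshold and, where they have one, their direction. The call was lost in 70 and gained in 68, and 52 changed sign. Ranges in the time courses have no sign, so only the light hours and the nights of DD could change sign. The rule also names genes for large changes in these same data. The nights of LD, where named genes that did not pass also changed sign between scalings, are outside the 4928 values. The light-hours count lay between 84 and 91 without any 1 culture, and its median moved from 0.78 to 2.23 on unscaled signal. Unscaled signal here also leaves out the LD 8 h B sample, 2 choices together; without that sample alone the median was 0.78 and, of the named genes, only Sigma70.1b changed sign in the light hours.

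As replicate letters share only a number, pairing was checked and not used: deviations of LD and DD cultures with the same letter correlated across transcripts at r of 0.147, 0.254 and 0.0476. Cultures with different letters ranged from -0.282 to 0.215, so these values do not settle whether letters pair. With the replicate block, 91 transcripts passed in the light hours and 37 kept their timing; with culture as a random block, at a correlation of 0.222, 86 and 35.

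Except where samples were fewer, the cause was not tested for what follows. At -8 h the count became 1 under TMM, median of ratios, without Actin12, and with either sample weights, and spanned 0 to 1 without 1 culture (1 without DD replicate C). The nights of LD gave 11 (without LD replicate A) to 21 without 1 culture, 8 with DD A as labelled and 32 with REML weights. At 24 h the count was 25 with DD A as labelled. As labelled, its DD 24 h column holds the LD 24 h signals of replicate A in 104 of 104 transcripts. That contrast therefore set LD signals in part against LD signals. The shared dark hours gave 0 to 1 without 1 culture (1 without LD replicate B) and 1 on unscaled signal. Kept timing counted 23 with the last 24 h only and 31 to 33 without 1 culture. With an estimated correlation camera's adjusted p was 0.317 for heat shock factors in the light hours, and 0.0613 for bHLH and 0.297 for other transcription factors between DD nights.

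In the light hours these changed sign (log2): bHLH1a_PAS to -0.047 under median of ratios, and on unscaled signal bHLH3 to 0.57, bZIP14 to 0.78, bZIP7_PAS to 0.35, CCCH8 to 0.21, HSF3.3a to 0.44, HSF3.3f to 0.56 and psbC to 0.71. Sigma70.1b, at 0.02 and not called, went to -0.50 under TMM, -0.71 under median of ratios, -0.31 without Actin12, -0.32 without the LD 8 h B sample, -0.32 with REML and -0.31 with gene-by-gene weights and -0.042 with pseudocount 10, and spanned -0.35 to 0.23 without 1 culture.

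Between the nights of DD, median of ratios turned bZIP14 to 0.20, bZIP18 to 0.41, bZIP5_PAS to 0.17, HSF1a to 0.025, HSF2.1a to 0.20, HSF3.3f to 0.23 and Lhcx1 to 0.14, and TMM bZIP18 to 0.026. Without Actin12, bZIP14 went to 0.56, bZIP18 to 0.77, bZIP5_PAS to 0.53, HSF1a to 0.39, HSF2.1a to 0.56, HSF3.3a to 0.24, HSF3.3f to 0.58, Lhcx1 to 0.50 and Myb5R to 0.34. Without Rps, bZIP26 went to -0.75 and Myb1R_SHAQKYF6 to -0.36, and without Tbp bZIP26 to -0.038. Unscaled signal gave -1.07 for bZIP26, -0.11 for bZIP6_PAS, -0.22 for HSF1g, -0.69 for Myb1R_SHAQKYF6 and -0.11 for Myb3R1. With DD A as labelled, bZIP14 went to 0.25, bZIP5_PAS to 0.046, HSF3.3f to 0.35 and Lhcx1 to 0.071. For bZIP26, REML weights gave -0.062, gene-by-gene weights -0.030 and pseudocount 10 -0.17. Without 1 culture bZIP26 spanned -0.15 to 0.29 and bZIP18 -0.18 to 0.00653.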

Other observations

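No tests were run here, and these genes were set side by side after their values were seen. In DD, bHLH1a_PAS and bHLH1b_PAS rose at the hours of the absent light but did not return to their levels at 0 h, and were at 8.66 ± 0.12 and 9.69 ± 0.12 log2 at 24 h, against 5.68 ± 0.23 and 5.26 ± 0.19 in LD (SD, n = 3). In contrast bZIP5_PAS both fell and returned in DD, from 11.61 ± 0.15 at 0 h to 7.25 ± 0.17 at 12 h and 12.32 ± 0.30 at 24 h. GapC1, which reached 13.20 ± 0.18 at 24 h in LD, was at 7.07 ± 0.32 in DD.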
